A study of Gallus gallus with 3 samples.

How the data were processed

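Single-cell libraries were made with the 10x Genomics 3' kit, version 3.1, and read with Cell Ranger 4.0.0 against the chicken genome build GRCg6a, per the submitters' processing notes. The authors deposited a table of UMI counts per gene and cell for each library, without normalization, and 1 annotation table for all cells. The tables hold 16748 genes, of which 12430 carry a symbol and 4318 an identifier only, and 3262 cells with 29680661 UMIs. As deposited, the annotation gives percent of UMIs in mitochondrial genes and percent in ribosomal protein genes, computed by the authors for each cell. It also gives the UMIs per cell, a cell cycle phase, a first-level class (13 names) and a finer class (12 names) that 980 cells lack. The mitochondrial and depth limits applied by the authors are not stated, and the highest mitochondrial value present was 9.97%. Summed counts equalled the annotated UMIs per cell exactly in 84.4% of cells, and the largest difference was 9 UMIs. The other 9 annotation columns were not used here.

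The finer class was used where present and the first-level class otherwise. Lateral plate and limb mesenchyme was the union of 7 classes whose name holds these words or most of whose cells lie in such a first-level class. Somatopleure was included, with 91.4% of its cells in the first-level lateral plate class, and amnion was left out, with 45.8%. This last rule was set after the annotation was seen, and its alternatives are reported. Cells without a finer class included ectoderm, blood vessel and low count cells.

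UMI counts were summed over the cells of a class in a library and divided by all UMIs of those cells, giving CPM with exact Poisson intervals. Folds between sums carry exact conditional binomial intervals, and shares of cells exact Clopper-Pearson intervals, all at 95%. A count of 0 is given with the limit that 3 counts over the group would set, and a fold against 0 is a lower bound computed with those 3 counts. A gene was measured with 30 or more UMIs in the 2 sums together, and a fold of 2 was used as a description of size. Classes needed 20 cells. Shares of cells with a UMI were computed after thinning each cell to 2800 UMIs, the 10th percentile over mesenchyme cells rounded down, with 4200 UMIs, the 25th percentile, as the alternative.

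The comparisons, gene lists, named genes and most alternatives were fixed before the data were examined. For each pair of stages, the named genes were the 10 with the highest and the 10 with the lowest fold. They were ranked by the interval bound nearest to 1, among genes with a symbol and 100 or more UMIs. Haemoglobin, mitochondrial (13) and ribosomal protein (73) genes and 3 W-linked genes were left out of the ranking. Up to 4 members of each list with the largest absolute log2 fold, and a fixed set of limb and lateral plate genes, completed the rule. A few other list members and class genes were named after their values were seen, among them DISP1, GAS1, PFKL, UHRF1, ECT2, CENPF, COL4A1 and KRT18.

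The 25 lists held 540 genes, 477 of them present. They cover lateral plate mesoderm, somatic layer, splanchnic layer, forelimb initiation, hindlimb identity, limb patterning, 3' HOX, middle and 5' HOX, epithelial, mesenchymal, and extracellular matrix genes. They also cover FGF, WNT, BMP and TGF-beta, Hedgehog, Notch and retinoic acid pathways, cartilage with tendon and connective tissue, early embryonic progenitors, S phase, G2/M phases, cell cycle exit, glycolysis, immediate early with heat shock, and haemoglobin genes. Lists overlap: forelimb, limb patterning and somatic layer lists share TBX5, MSX1 or TWIST1, for example. The median log2 fold of a list was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. A further 15 lists of cell type markers named the new clusters.

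In a self-test, known folds were put into simulated libraries at the depths of these. A 3-fold difference was recovered past 2-fold in 100%, 96.9% and 99.0% of the changed genes for HH10 with HH14, HH14 with HH18 and HH10 with HH18, and an 8-fold difference in 100%. Unchanged genes passed 2-fold in 0.647%, 0.701% and 0.649% of cases, and their intervals covered the true value in 95.6%, 95.8% and 95.5%. The sums were drawn from the Poisson model that the intervals assume, with no spread between cells. This coverage therefore checks the computation and not the model. The self-test was not run at the smaller and unequal depths of single classes, so it gives no rate of unchanged genes past 2-fold there. Scrublet, as implemented in scanpy with an expected rate of 2%, called 1 doublet per library and 0 among lateral plate and limb mesenchyme.

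The alternatives were median-of-ratios scaling, totals without haemoglobin, mitochondrial and ribosomal protein genes, the mean over cells, thinned cells, minima of 10 and 100 UMIs, all annotated cells, doublets left out, a fold of 4, and cells in S or G2/M phase left out, with phases called here on thinned cells. Added after the data were seen were somatopleure left out, amnion added, splanchnic and extraembryonic classes left out, cells with 5 or more or with 0 UMIs of HINTW, and median-of-ratios scaling between classes. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.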

Results

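Single-cell RNA profiles were collected from the forelimb field of wild-type chicken embryos, the tissue beside the somites from which the wing bud arises. Tissue was taken at Hamburger-Hamilton (HH) stages 10, 14 and 18, chick embryo stages defined by external anatomy, with stage 10 labelled as embryonic day 1.5 and each later stage as 1 day more. Each stage was 1 library made from pooled male and female embryos, so no stage had a replicate and no test between stages was made. The HH10 library held 1210 cells and 11855255 unique molecular identifiers (UMIs, each a tagged RNA molecule), the HH14 library 1313 cells and 11267879 UMIs, and the HH18 library 739 cells and 6557527 UMIs. The median cell had 7799, 6641 and 5994 UMIs at HH10, HH14 and HH18. Lateral plate mesoderm, the sheet that splits into a somatic layer toward the body wall and a splanchnic layer toward the gut, and the limb mesenchyme that forms from its somatic layer are together called lateral plate and limb mesenchyme here. This population had 599, 598 and 325 cells, with 5034976, 5375480 and 3547593 UMIs. Levels are UMIs of a gene on the counts-per-million scale (CPM) within the cells summed. All intervals in parentheses, binomial for shares and Poisson or conditional binomial for counts, are exact 95% intervals for counting error only, and differences between libraries hold for these libraries and carry no measure of the spread between embryos or pools.

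The cell classes present in the forelimb field differed between the libraries. In the authors' annotation, the HH10 library was led by a class called here undifferentiated cluster 7, with 427 of 1210 cells (35.3%, interval 32.6 to 38.1), and by primitive mesoderm, with 301 cells (24.9%, 22.5 to 27.4). Limb bud mesenchyme was at 0 of 1210 cells at HH10, which allows a share of up to 0.248%, at 21 of 1313 cells at HH14 (1.60%, 0.993 to 2.43) and at 180 of 739 cells at HH18 (24.4%, 21.3 to 27.6). Splanchnic lateral plate made up 1.49% of cells at HH10 (0.884 to 2.34), 16.4% at HH14 (14.4 to 18.5) and 2.84% at HH18 (1.77 to 4.31). Somatopleure, a name for the somatic layer with its overlying ectoderm, made up 1.24%, 12.6% and 10.1% at the successive stages. Primitive streak cells were 29 of 1210 at HH10 and 0 at HH14 and at HH18, where counts of 0 allow up to 0.228% and 0.406%. Amnion cells made up 0.331%, 9.44% and 8.39%, and the second of the ectoderm clusters was at 0 of 1210 cells at HH10, 5.71% at HH14 and 14.5% at HH18.

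Within lateral plate and limb mesenchyme, undifferentiated clusters 7 and 1 held 71.3% (67.5 to 74.9) and 22.0% (18.8 to 25.6) of the HH10 cells. At HH14 the largest classes were splanchnic lateral plate with 36.0% (32.1 to 39.9), somatopleure with 27.6% (24.0 to 31.4) and extraembryonic lateral plate with 14.2% (11.5 to 17.3). Limb bud mesenchyme held 55.4% of the HH18 cells (49.8 to 60.9), somatopleure 23.1% (18.6 to 28.0) and flank lateral plate 12.3% (8.94 to 16.4). The classes were drawn by the authors from the same expression values, so these shares describe the annotation, and dissection of a different extent at each stage would set them too. Folds between stages below are over the sum of these classes. They can reflect a changed class mix as well as changed levels within a class. With all libraries clustered anew together and clusters named by fixed markers, the share named limb and lateral plate mesenchyme was 6.03%, 30.1% and 58.5%, against 49.5%, 45.5% and 44.0% in the annotation. The cells differ from the annotated ones. At HH10, 67 of the 73 cells so named lay in a cluster whose most common annotated class was low count cells, with 2.5% annotated as lateral plate or limb, and most annotated cells lay in clusters named intermediate mesoderm or left unnamed. At HH14 that cluster and 1 whose most common class was amnion, with 10.5% annotated as lateral plate or limb, held 93 and 105 of the 395 cells so named, and at HH18 80 and 45 of 432, so the shares of the clustering and of the annotation are of different populations at each stage.

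**Figure D1:**
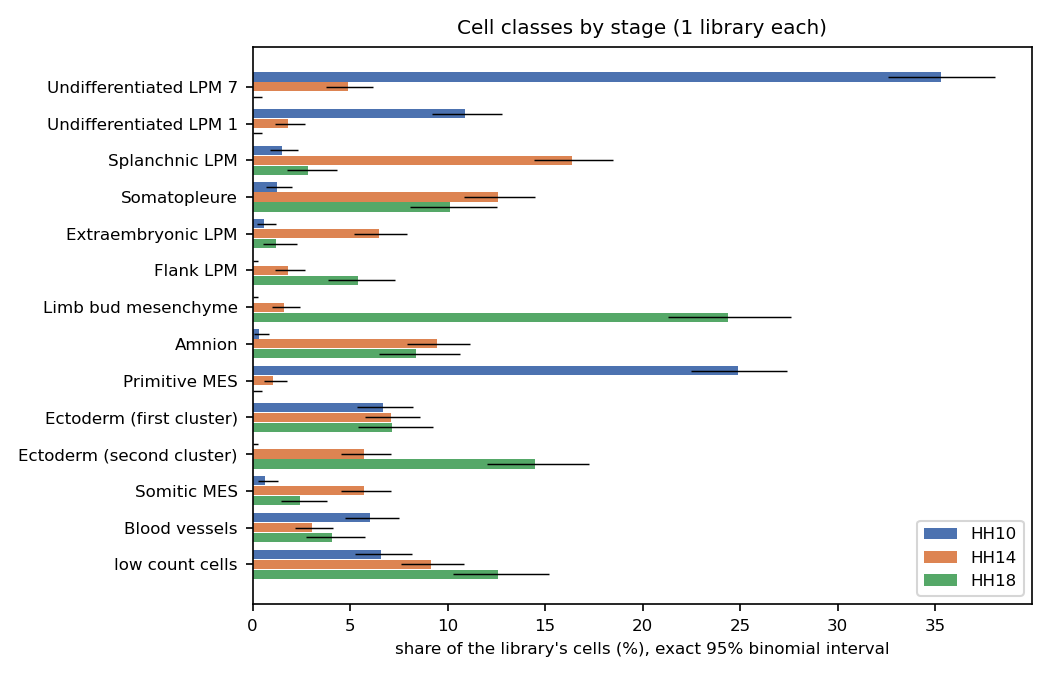
Share of each library's cells in 14 classes of the authors' annotation (horizontal axis, percent), with 1 bar per stage and exact 95% binomial intervals for counting error as error bars. Undifferentiated cluster 7 leads at HH10 with 35.3%, splanchnic lateral plate at HH14 with 16.4% and limb bud mesenchyme at HH18 with 24.4%.

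The comparison of HH10 with HH14 covers the time before the wing bud is visible. In the HH14 lateral plate and limb mesenchyme, some transcription factors of the somatic layer and of the gut mesenchyme were higher than at HH10, while HAND2, of the splanchnic list, was 2.01-fold higher at HH10 and FOXF1 1.72-fold (1.37 to 2.17), short of 2-fold. TBX5, the T-box factor that starts forelimb outgrowth, had 4 UMIs at HH10 and 135 at HH14 (31.6-fold higher, 12.1 to 118). NKX3-2, a homeobox gene of gut mesenchyme and of the spleen primordium, had 4 and 275 UMIs (64.4-fold higher, 24.9 to 238), and IRX3, an Iroquois homeobox gene, was 18.6-fold higher (12.4 to 29.0). TWIST1, a basic helix-loop-helix factor of mesenchyme, stood at 14.3 CPM at HH10 and 146 CPM at HH14 (10.2-fold, 8.03 to 13.2), and the matrix proteoglycan gene DCN at 42.7 and 318 CPM. Among the genes higher in the HH10 library, CDX4, a caudal homeobox gene of the posterior body, was 17.5-fold higher there (13.8 to 22.7), EVX1, a homeobox gene of the primitive streak and tail bud, stood at 89.0 CPM at HH10 and 5.58 CPM at HH14, and Pou5f3, the chick relative of the pluripotency gene OCT4, was 5.14-fold higher at HH10 (4.39 to 6.04).

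Among the other genes ranked highest at HH14 were SMOC2, a secreted matrix protein (37.8-fold, 12.6 to 186), PKDCC, a secreted kinase (16.6-fold, 7.82 to 42.1), PDZRN4 (12.3-fold, 8.55 to 18.2), TAGLN, an actin-binding protein of smooth muscle (11.8-fold, 6.21 to 25.2), and JUN, an immediate early transcription factor (11.4-fold, 9.54 to 13.7). Ranked highest at HH10 were also CLEC19A (15.1-fold, 12.2 to 18.9), SS2 (11.8-fold, 6.55 to 23.5), the proprotein convertase PCSK5 (5.92-fold, 4.65 to 7.62), SMOC1 (5.85-fold, 4.43 to 7.84), the chemokine CXCL12 (5.55-fold, 4.73 to 6.56), PIWIL1, a Piwi protein of small RNA pathways (4.49-fold, 3.44 to 5.92), and the somatostatin gene SST (4.32-fold, 3.57 to 5.26).

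By list, 5 of 9 measured somatic layer genes were at least 2-fold higher at HH14 and 1, MSX1, was lower, with a median log2 fold of 1.45 (percentile 100 among 10000 random lists matched on size and mean expression). Of 9 splanchnic layer genes 3 were higher, among them the gut homeobox genes BARX1 (14.4-fold, 4.62 to 72.2) and NKX2-3 (3.07-fold, 1.79 to 5.53), and 1, HAND2, was lower at HH14, at a median log2 fold of 0.67 (percentile 99.99). Forelimb initiation genes had a median log2 fold of 0.82, with 6 of 17 higher and 2 lower. Besides TBX5 and TWIST1, HOXC4 was 11.8-fold higher (4.80 to 37.6) and WNT2B, a WNT ligand placed upstream of wing outgrowth, 5.35-fold (2.37 to 14.2). Limb patterning genes were higher in 4 of 18 cases and lower in 4, at a median of -0.11 (percentile 2.93). Mesenchymal genes had 9 of 23 members higher and 1 lower, and extracellular matrix genes 10 of 30 higher and 3 lower, at medians of 0.82 and 0.60. The collagen genes COL6A3 (7.81-fold, 3.35 to 22.3) and COL12A1 (4.62-fold, 2.57 to 8.88) and the matrix protein gene POSTN (3.75-fold, 1.90 to 8.04) were among them. In the retinoic acid pathway, RDH10 and ALDH1A2, which make retinoic acid from retinol in successive steps, were higher at HH14, at 21.7 and 163 CPM for RDH10 and at 132 and 398 CPM for ALDH1A2. The degrading enzyme CYP26B1 was lower there, at 6.36 CPM at HH10 and 1.67 CPM at HH14. Over the pathway, 3 of 15 genes were higher and 2 lower, at a median log2 fold of 0.65 (percentile 100).

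Hedgehog pathway genes were higher in 4 of 12 cases at HH14 and lower in 0, at a median log2 fold of 0.58 (percentile 99.97). With cells thinned to equal depth their median was -0.03. Thinning lowered the number of measured genes over all lists and other genes from 9166 to 6793. The thinned median can therefore be over fewer Hedgehog genes, and the change cannot be read as an effect of depth alone. The higher genes were the antagonist HHIP, at 1 and 41 UMIs (38.4-fold, 6.52 to 1553), the co-receptors BOC (3.35-fold, 2.54 to 4.47) and GAS1 (2.91-fold, 2.23 to 3.86), and DISP1, needed for ligand release (2.01-fold, 1.42 to 2.88). Immediate early and heat shock genes were higher in 4 of 17 cases at a median log2 fold of 0.57, with FOS 4.86-fold (2.82 to 8.89), EGR1 2.67-fold (1.38 to 5.47) and KLF6 2.31-fold (1.76 to 3.05) higher beside JUN. Early embryonic progenitor genes were lower in 4 of 15 cases at HH14, at a median log2 fold of -0.31 (percentile 0.01). MSGN1, a factor of presomitic mesoderm, had 48 and 2 UMIs (25.6-fold higher at HH10, 6.72 to 218), and TBXT, the Brachyury gene, was 2.53-fold higher at HH10. Middle and 5' HOX genes were lower in 3 of 12 cases, HOXA7 (3.24-fold higher at HH10), HOXB8 (2.94-fold) and HOXB9 (2.88-fold), at a median log2 fold of -0.24 (percentile 0.36), while 3' HOX genes were higher in 2 of 13 cases at a median of 0.29 (percentile 99.6). The FGF pathway had 1 gene higher and 4 lower of 19 at HH14. The lower ones included the feedback regulators SPRY2 (3.93-fold higher at HH10) and DUSP6 (2.69-fold) and the ligand FGF18 (2.94-fold).

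Over all 9166 measured genes, 398 were at least 2-fold higher in the HH14 library and 236 lower, and the median log2 fold was 0.05. With the splanchnic and extraembryonic classes left out, an alternative chosen after the data were seen, 220 were higher and 353 lower, with 298 of the 598 HH14 cells kept. MSX1, a homeobox gene of limb and amnion, was 3.23-fold higher at HH10 in this population. Its log2 fold of HH14 over HH10 was 0.04 over all annotated cells and 0.20 with amnion cells added, and that of CYP26B1 was 0.82 over all annotated cells.

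The comparison of HH14 with HH18 covers the emergence of the wing bud. At HH18 all measured genes of the somatic layer and many of limb patterning and of middle and 5' HOX genes were higher, and most of the splanchnic layer lower. Splanchnic lateral plate made up 36.0% of this population at HH14 and 6.46% at HH18, and limb bud mesenchyme 3.51% and 55.4%. The folds over the whole population carry this change of class mix. LMX1B, the LIM homeobox gene of dorsal limb mesenchyme, had 6 and 184 UMIs (46.5-fold higher at HH18, 20.9 to 128), and RSPO2, a secreted enhancer of WNT signalling needed for limb growth, 11 and 166 UMIs (22.9-fold, 12.5 to 46.7). CRABP-I, which binds retinoic acid in the cytoplasm, stood at 42.0 CPM at HH14 and 884 CPM at HH18 (21.0-fold, 18.4 to 24.2). TBX5 was a further 5.67-fold higher (4.68 to 6.91), at 25.1 and 142 CPM, and PRRX1, the paired-related homeobox gene of limb mesenchyme, 2.90-fold (2.78 to 3.03), at 630 and 1828 CPM. The gut mesenchyme genes NKX3-2 (12.1-fold, 7.21 to 21.9), HLX (19.0-fold, 7.96 to 59.4) and TCF21, a factor of coelomic epithelium and visceral mesenchyme (8.19-fold, 5.90 to 11.7), were higher at HH14.

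Genes ranked highest at HH18 also included EBF3 (16.5-fold, 9.51 to 30.8), the paired-related homeobox gene PRRX2 (14.8-fold, 8.54 to 27.8), the WNT inhibitor WIF1 (11.4-fold, 8.07 to 16.7), HOXD9 (10.6-fold, 7.21 to 16.1), HOXA9 (6.72-fold, 5.58 to 8.15) and the glypican gene GPC3 (6.54-fold, 5.41 to 7.95). The other genes ranked highest at HH14 were SST, with 133 UMIs at HH14 and 0 at HH18 (at least 29.3-fold higher against the limit of 3 counts), the guidance ligand SEMA3D (28.8-fold, 12.1 to 89.5), CSRP1, a LIM protein of smooth muscle (79.8 and 5.36 CPM), IFI27L2 (13.2-fold, 5.89 to 36.7), the transthyretin gene TTR (12.1-fold, 8.30 to 18.2), the NODAL co-receptor CFC1 (10.5-fold, 6.62 to 17.7) and LINGO1 (9.98-fold, 4.91 to 23.6).

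All 12 somatic layer genes were at least 2-fold higher at HH18, at a median log2 fold of 1.85 (percentile 100). EMX2 (7.07-fold, 2.87 to 20.9) was among them. Limb patterning genes were higher in 12 of 21 cases and lower in 1, at a median of 1.36. HOXD10 had 1 and 85 UMIs (129-fold, 22.5 to 5146), and LHX2, a LIM homeobox gene of distal limb mesenchyme, 6 and 90 UMIs (22.7-fold, 10.0 to 63.6). Middle and 5' HOX genes were higher in 8 of 13 cases, HOXD8 4.61-fold (3.79 to 5.64), and 3' HOX genes in 3 of 13, HOXC5 (2.62-fold, 2.10 to 3.28), HOXA5 (2.52-fold, 2.25 to 2.83) and HOXD3 (2.28-fold, 1.95 to 2.67). Their medians were 1.31 and 0.45. Forelimb initiation genes were higher in 9 of 19 cases at a median of 0.85 (percentile 100), and mesenchymal genes in 5 of 23 at 0.21, with COL1A1 at 140 and 367 CPM. Splanchnic layer genes were lower in 6 of 9 cases and higher in 0, at a median log2 fold of -1.30 (percentile 0). GATA4, a factor of heart and gut mesoderm, was 9.64-fold higher at HH14, FOXF1, the forkhead gene of splanchnic mesoderm, 8.12-fold (4.27 to 17.4), and BARX1 3.04-fold. Lateral plate mesoderm genes, which share several members with that list, were lower in 5 of 11 cases at a median of -0.36. In the hindlimb identity list the LIM homeobox gene ISL1 had 59 UMIs at HH14 and 1 at HH18 (38.9-fold higher at HH14, 6.72 to 1564), while HOXC9 was 3.46-fold higher at HH18 (2.65 to 4.54).

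FGF pathway genes were higher in 7 of 19 cases at HH18 and lower in 2, at a median log2 fold of 0.48 (percentile 100). The ligand FGF9 had 4 UMIs at HH14 and 29 at HH18, the membrane proteins FLRT2 and IL17RD were 4.24-fold (2.77 to 6.67) and 3.77-fold (2.57 to 5.61) higher, and the decoy receptor FGFRL1 was 7.75-fold higher at HH14. In the WNT list 6 of 30 genes were higher and 4 lower. WNT11, a ligand of the non-canonical branch, had 39 UMIs at HH14 and 1 at HH18 (25.7-fold higher at HH14, 4.36 to 1042). In the retinoic acid list 3 of 15 were higher and 2 lower. CYP26A1, a retinoic acid hydroxylase, was 8.95-fold higher at HH18 (4.69 to 18.8), and RDH10 was 2.91-fold higher at HH14. Immediate early and heat shock genes were lower in 6 of 17 cases at HH18, at a median log2 fold of -0.33 (percentile 0), with EGR1 (6.10-fold), ATF3 (5.52-fold), FOS (2.74-fold) and GADD45B (2.53-fold) higher at HH14. In the Hedgehog list 2 of 13 were higher and 3 lower, in the Notch list 2 of 12 higher and 2 lower, and in the BMP and TGF-beta list 2 of 27 higher, MSX2 (3.70-fold, 3.14 to 4.37) and MSX1 (2.94-fold, 2.45 to 3.55), and 3 lower. Epithelial genes were lower in 4 of 15 cases and higher in 0, with the keratin gene KRT18 at 1143 CPM at HH14 and 471 CPM at HH18, while the list's median log2 fold was 0.18 (percentile 84.2). In that list CLDN1 and CLDN3 had log2 folds of HH18 over HH14 of 0.46 and 0.17 over all annotated cells, against the lower levels at HH18 in this population. Cartilage, tendon and connective tissue genes were higher in 3 of 8 cases, SOX8 15.4-fold (7.08 to 39.6), and lower in 2, OSR1 and SOX9.

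Over all 9064 measured genes, 336 were at least 2-fold higher at HH18 and 271 lower, with a median log2 fold of 0.09. After median-of-ratios scaling 277 were higher and 300 lower, so the larger direction depended on the scaling. With the splanchnic and extraembryonic classes left out, chosen after the data were seen, the counts were 418 and 124. Within a class, 131 genes were higher at HH18 and 169 lower in somatopleure, and 339 and 545 in splanchnic lateral plate. The counts were 471 and 123 in limb bud mesenchyme and 202 and 27 in flank lateral plate, with 21 and 24 cells of these 2 classes at HH14. Splanchnic lateral plate had 21 cells at HH18. The class sums were unequal in depth, with 317493 UMIs at HH14 and 2451866 at HH18 in limb bud mesenchyme. How many unchanged genes pass 2-fold at such depths was not tested, so the larger direction within a class cannot be read as a change of level.

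HH10 and HH18 are the ends of the series, and TBX5 ranked first among the genes higher at HH18. It was 179-fold higher at HH18 (69.6 to 660). WIF1 had 1 and 272 UMIs (386-fold, 68.7 to 15303), IRX5 2 and 207 UMIs (147-fold, 40.2 to 1221), EBF3 2 and 152 (108-fold, 29.4 to 899), and the serpin gene SERPINF1 2 and 102 (72.4-fold, 19.5 to 606). PRRX2 had 0 and 137 UMIs, at least 64.8-fold higher against the limit of 3 counts. LMX1B was 87.0-fold higher (29.3 to 426), RSPO2 58.9-fold (22.6 to 219), IRX3 41.8-fold (28.1 to 65.0) and TWIST1 35.8-fold (28.2 to 45.9). CDX4 had 1150 UMIs at HH10 and 1 at HH18 (810-fold higher at HH10, 145 to 32032), and SST 538 and 0 UMIs (at least 126-fold). The other genes ranked highest at HH10 were TNNT2, a troponin of cardiac muscle (118-fold, 20.8 to 4675), WNT11 (81.0-fold, 14.3 to 3228), CLEC19A (80.6-fold, 44.9 to 162), CSRP1 (36.7-fold, 23.4 to 61.2), SS2 (31.2-fold, 10.5 to 153), CFC1 (24.2-fold, 15.4 to 40.5), CXCL12 (184 and 9.02 CPM) and the semaphorin and VEGF receptor gene NRP1 (16.1-fold, 11.3 to 23.9).

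Somatic layer genes were higher in 11 of 12 cases between these libraries, at a median log2 fold of 4.02, forelimb initiation genes in 12 of 19 at 1.32, limb patterning genes in 13 of 21 at 1.28, middle and 5' HOX genes in 9 of 13 at 1.23 and mesenchymal genes in 12 of 23 at 1.12 (percentile 100 for each). In these lists 0, 1, 4, 1 and 2 genes were lower. Retinoic acid pathway genes were higher in 8 of 17 cases and lower in 1, at 0.89, with CYP26A1 at 0 and 65 UMIs, and Hedgehog pathway genes higher in 5 of 12 and lower in 2, at 0.57, with BOC 6.02-fold higher. Extracellular matrix genes were higher in 12 of 31 cases and lower in 3, with LAMA4 at 0 and 57 UMIs and COL6A3 23.9-fold higher (10.6 to 66.6). Splanchnic layer genes were lower in 3 of 7 cases at -0.80 (percentile 0.03). Early embryonic progenitor genes were lower in 4 of 15 cases at -0.28, including the RNA-binding LIN28A (5.40-fold higher at HH10) and MYC (4.62-fold). Cell cycle exit genes had 1 of 7 higher, GAS1, and 0 lower. The glycolysis list had 0 of 18 genes higher and 1 lower, the phosphofructokinase gene PFKL (2.28-fold higher at HH10), at a median of -0.05. Over all 8953 measured genes 732 were at least 2-fold higher at HH18 and 373 lower, a split of 66.2% higher, and the median log2 fold was 0.14. After scaling by the median of gene ratios, which sets that median to 0.00, the counts were 577 and 455, a split of 55.9% higher. Over all annotated cells the log2 folds of HH18 over HH10 were 0.88 for CYP26B1, 0.67 for ITGA6 and -0.13 for FGF10, each with the sign opposite to that in this population.

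**Figure D2:**
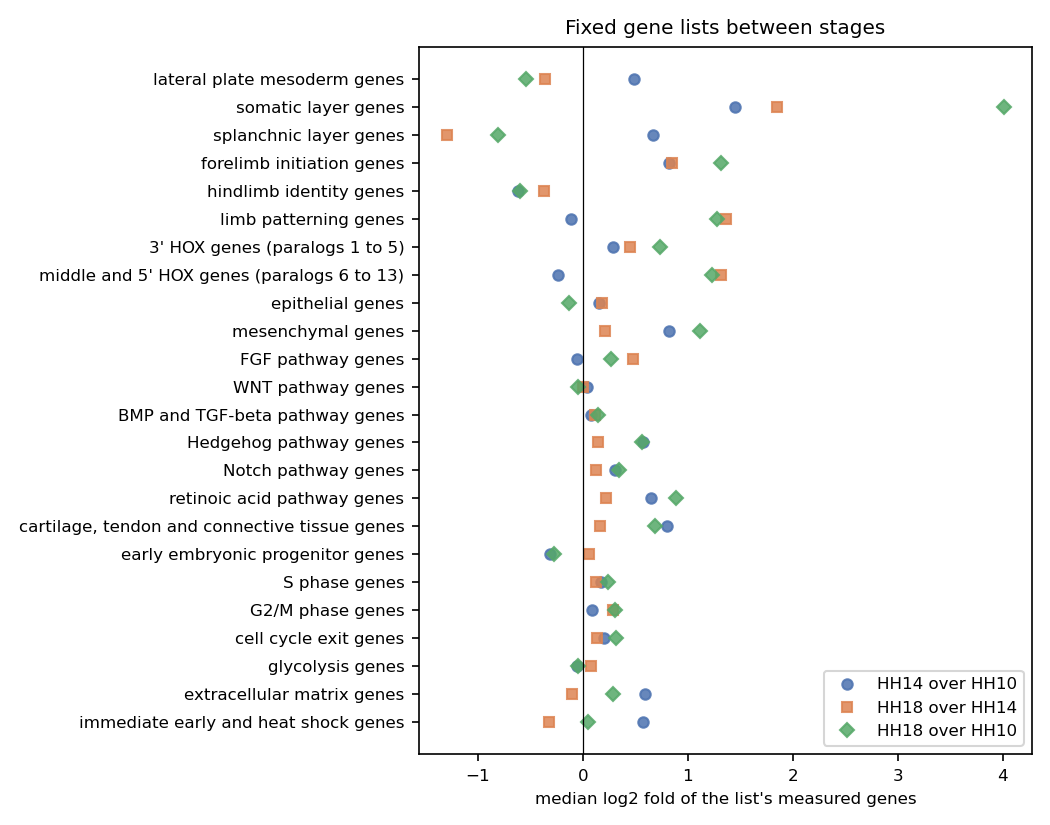
Median log2 fold of the measured genes of 24 fixed lists (horizontal axis) in lateral plate and limb mesenchyme, with 1 symbol per pair of libraries. Somatic layer genes have medians of 1.45, 1.85 and 4.02, and splanchnic layer genes 0.67, -1.30 and -0.80, for HH14 over HH10, HH18 over HH14 and HH18 over HH10.

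Haemoglobin genes, markers of red blood cells, moved with stage in the same cells. The haemoglobin genes together stood at 29.6 CPM at HH10, 988 CPM at HH14 and 799 CPM at HH18, and all 5 measured members were higher at HH14 than at HH10, at a median log2 fold of 5.73. The annotated red blood cells numbered 0, 19 and 4. In the HH14 population, the 6 cells with the most held 49.0% of the haemoglobin UMIs. Without them the level was 507 CPM at HH14, and without the 4 cells with the most it was 648 CPM at HH18 (622 to 675), so the order of HH14 and HH18 turned. The W-linked gene HINTW, which is read from the chromosome that female birds carry, also moved with stage, at 1584, 3779 and 3664 CPM over all cells at HH10, HH14 and HH18.

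A fixed set of genes known from limb and lateral plate development was followed across the stages. FGF10, the mesenchymal ligand that drives limb outgrowth, was at 11.9, 15.8 and 42.6 CPM at HH10, HH14 and HH18. The intervals of HH10 and HH14 overlapped, and HH18 was 2.69-fold above HH14 (2.05 to 3.55). ALDH1A2 was at 132, 398 and 331 CPM. MEIS1 and MEIS2, homeobox genes of proximal limb, were at 143, 267 and 305 CPM and at 261, 461 and 633 CPM. HAND2, a factor of lateral plate and posterior limb, was at 770, 383 and 372 CPM, and FOXF1 at 39.3, 22.9 and 2.82 CPM. PITX1, a hindlimb homeobox gene, was at 33.6, 8.37 and 6.48 CPM, and TBX4, the hindlimb T-box gene, had 0, 0 and 2 UMIs. SALL4 was at 149, 100.3 and 89.6 CPM, and LIN28B, a regulator of developmental timing, at 178, 213 and 226 CPM. SHH, the ligand of the limb polarizing region, had 1, 11 and 3 UMIs, and the BMP antagonist GREM1 1, 2 and 9 UMIs. HOXD13 was at 0 UMIs in each library, which allows up to 0.596, 0.558 and 0.846 CPM, and HOXA13 at 4, 0 and 0 UMIs, so differences in these genes were not detectable at this depth.

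**Figure D3:**
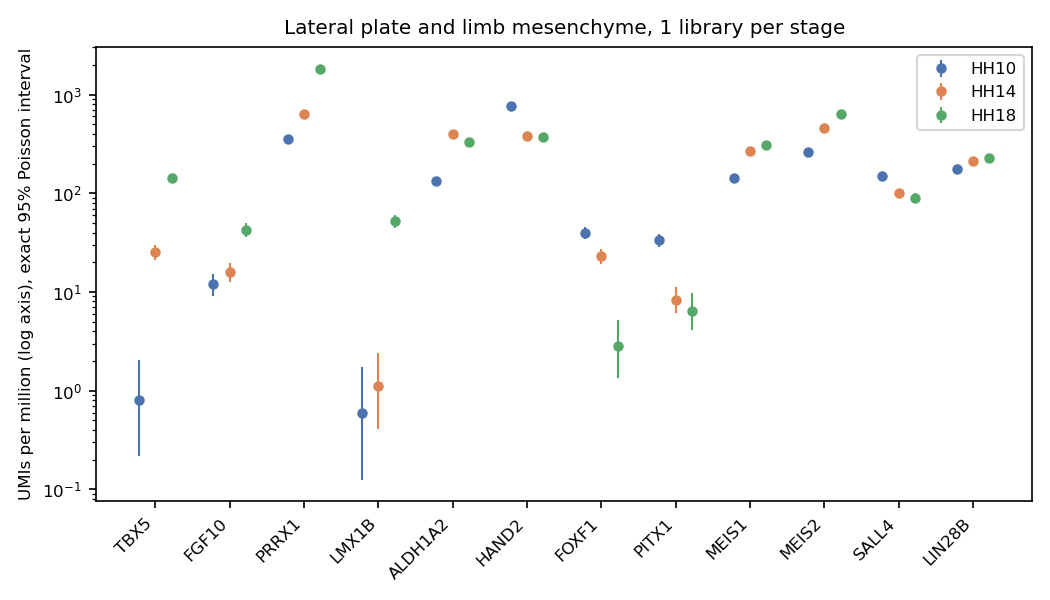
Level of 12 genes in lateral plate and limb mesenchyme (vertical axis, CPM on a log axis), with 1 point per stage and library and exact 95% Poisson intervals for counting error as bars. TBX5 lies at 0.794, 25.1 and 142 CPM and FOXF1 at 39.3, 22.9 and 2.82 CPM at HH10, HH14 and HH18.

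The share of cells with at least 1 UMI was compared after each cell was thinned to 2800 UMIs, which left out 55, 54 and 33 cells. TBX5 was found in 1 of 544 cells at HH10 (0.184%, 0.00465 to 1.02), 23 of 544 at HH14 (4.23%, 2.70 to 6.28) and 80 of 292 at HH18 (27.4%, 22.4 to 32.9). In blood vessel and red blood cells, taken as the background, it was found in 0 of 63, 0 of 49 and 1 of 23 thinned cells. The count of 0 at HH14 allows up to 6.12%, so the thinned HH14 share was not separable from background. Without thinning the TBX5 share was 0.668%, 14.2% and 52.3%, against 0 of 74, 1 of 63 (1.59%) and 2 of 37 (5.41%) background cells, at median depths of 6990, 7094.5 and 8236 UMIs in the mesenchyme and 5420, 4000 and 3705 in the background. PRRX1 was found in 55.7% (51.4 to 59.9), 56.1% (51.8 to 60.3) and 88.4% (84.1 to 91.8) of thinned mesenchyme cells and in 1.59%, 6.12% and 8.70% of thinned background cells. ALDH1A2 was found in 20.4% (17.1 to 24.0), 53.9% (49.6 to 58.1) and 47.9% (42.1 to 53.8), against 3.17%, 2.04% and 4.35% of the background. FGF10 was found in 3.13%, 3.49% and 8.90%, against 0 of 63, 1 of 49 and 0 of 23 background cells, where 0 of 63 allows up to 4.76% and 0 of 23 allows more, so none of these shares was separable from background at this depth. Without thinning the FGF10 shares were 8.51%, 10.7% and 28.0%, with intervals from 6.40%, 8.34% and 23.2% upward, against 0 of 74, 1 of 63 (0.0402 to 8.53) and 0 of 37 background cells, where counts of 0 allow up to 4.05% and 8.11%. The HH10 and HH18 shares lay above these limits, at the unequal depths given for TBX5. SHH was found in 0 of 544, 3 of 544 and 0 of 292 cells, and counts of 0 allow up to 0.551% at HH10 and 1.03% at HH18.

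Cell cycle genes took a larger part of the UMIs at later stages. S phase genes, 40 in all, were at 4847 (4786 to 4908), 5483 (5420 to 5546) and 5877 (5798 to 5958) CPM at HH10, HH14 and HH18, and 45 genes of the G2/M phases at 8127 (8048 to 8206), 8662 (8583 to 8741) and 9817 (9714 to 9920). No measured gene of either list, 40 and 43 genes, differed by 2-fold or more between any 2 libraries. The largest were the DNA methylation factor UHRF1 (1.71-fold higher at HH18 than at HH10, 1.57 to 1.86) and the cytokinesis factor ECT2 (1.66-fold, 1.31 to 2.10). In the authors' deposited phase calls, 20.4%, 11.7% and 16.6% of the mesenchyme cells were in S phase and 35.4%, 39.3% and 43.4% in G2/M phase. Calls made here on cells thinned to 2800 UMIs gave 30.1%, 31.1% and 32.2% in S phase and 66.9%, 63.8% and 65.1% in G2/M phase, with no rise in G2/M by stage.

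Classes within 1 library shared preparation and sequencing, and their differences describe the authors' annotation, which was drawn from the same values. Names of classes are the authors'. The 10 genes with the highest fold were taken over the cells of all libraries together. In flank lateral plate they held TBX5 and GATA6, the latter also on the lateral plate and splanchnic layer lists. Both are fixed markers of limb and lateral plate mesenchyme, of which the 10 genes of the next 3 classes held none. In somatopleure they held IRX3, a neural tube marker that is also on the lateral plate, somatic layer and limb patterning lists. In splanchnic lateral plate they held the mesothelium marker TCF21, and NKX3-2 and NKX2-3 of the splanchnic layer list. In limb bud mesenchyme they held LMX1B, LHX2 and HOXD10 of the limb patterning list and PRRX2 of the somatic layer list. The fixed marker PRRX1 was found in 99.4% of thinned bud cells at HH18. At HH14, the classes called somatopleure and splanchnic lateral plate differed in transcription factors, some of them on the layer lists. IRX3 was 13.3-fold higher in somatopleure (8.39 to 22.4), HOXA9 12.8-fold (5.09 to 41.5), PRRX1 7.81-fold (6.64 to 9.24) and TBX5 5.14-fold (2.39 to 12.3), while NKX3-2 was 21.6-fold (10.8 to 50.6), FOXF1 16.1-fold (6.09 to 60.3) and GATA4 7.91-fold (3.21 to 25.3) higher in splanchnic cells. Extracellular matrix genes were lower in somatopleure in 16 of 28 cases and higher in 0, with COL4A1 at 73.3 CPM in splanchnic cells and 9.64 CPM in somatopleure. These classes also differed in depth, with a median of 5335 UMIs per somatopleure cell and 7183 per splanchnic cell. Haemoglobin genes were at 953 CPM in somatopleure, or 675 CPM without its cells among the 6 with the most in the population, and at 491 CPM in splanchnic cells. Of 6846 genes 120 were at least 2-fold higher in somatopleure and 660 in splanchnic cells. After median-of-ratios scaling, which shifts the median log2 fold from -0.11 to 0.00, the counts were 162 and 519.

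At HH18, limb bud mesenchyme differed from somatopleure in RSPO2 (5.78-fold higher in the bud, 2.21 to 21.5), LMX1B (5.54-fold, 2.33 to 17.3), TBX5 (2.75-fold, 1.79 to 4.44) and the mitosis gene CENPF (5.45-fold, 3.72 to 8.31). Genes of the G2/M phases were higher in the bud in 18 of 43 cases. The classes also differed in depth, with a median of 3395 UMIs per somatopleure cell and 10313.5 per bud cell, and in haemoglobin genes, at 2272 and 586 CPM, or 943 CPM in somatopleure without the 3 cells among the 4 with the most haemoglobin in the population. KRT18 was at 719 CPM in somatopleure and 160 CPM in the bud. Of the measured genes 960 were higher in the bud and 105 lower, a split of 90.1% higher at a median log2 fold of 0.23, and after median-of-ratios scaling 612 and 256, a split of 70.5%. The sums held 388120 UMIs in somatopleure and 2451866 in the bud, and how many unchanged genes pass 2-fold at these depths was not tested. From flank lateral plate, the bud differed in LMX1B (17.1-fold higher in the bud, 4.66 to 142), MSX1 (6.63-fold, 3.45 to 14.6) and HOXD10, at 0 and 76 UMIs (at least 4.94-fold higher). TBX5 was at 196 CPM in flank and 156 CPM in the bud (1.26-fold higher in flank, 0.995 to 1.58), and GATA5 (8.89-fold, 6.89 to 11.5) and HAND1 (4.45-fold, 3.81 to 5.21) were higher in flank. Of 4 measured splanchnic layer genes 3 were at least 2-fold higher in flank and 0 lower. Between these classes 354 genes were higher in the bud and 318 in flank. After median-of-ratios scaling the counts were 321 and 343, so the larger direction depended on the scaling.

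Between limb bud mesenchyme of HH14, 21 cells, and of HH18, 180 cells, TBX5 was 1.60-fold higher at HH18 (1.11 to 2.38), against 5.67-fold in the whole population, and FGF10 was at 50.4 and 53.0 CPM (1.05-fold, 0.624 to 1.90), so no difference in FGF10 was detectable. After thinning to 2800 UMIs, TBX5 was found in 4 of 21 of these cells at HH14 (19.0%, 5.45 to 41.9) and 56 of 175 at HH18 (25.2 to 39.5), and FGF10 in 14.3% (3.05 to 36.3) and 10.9% (6.66 to 16.4), with overlapping intervals. Without thinning, at median depths of 12496 and 10313.5 UMIs, TBX5 was found in 66.7% and 68.9% and FGF10 in 52.4% and 40.6%. MSX1 was at 9.45 CPM at HH14 and 125 CPM at HH18, and LMX1B at 9.45 and 71.4 CPM. Both HH14 levels equal the limit of 3 counts over the 317493 UMIs of this class, so the size of these differences is poorly determined. HOXA9 was at 34.6 and 188 CPM and CRABP-I at 239 and 1073 CPM, while ALDH1A2 was at 535 and 241 CPM. At HH10, undifferentiated cluster 1 had higher levels than cluster 7 of HAND1 (3.14-fold, 2.84 to 3.48), FOXF1 (2.70-fold, 2.01 to 3.65), GATA6 (2.58-fold, 2.05 to 3.25) and the collagen gene COL3A1 (10.8-fold, 6.63 to 18.5). Other lists moved the same way. Epithelial genes were higher in cluster 1 in 4 of 11 cases and mesenchymal genes in 11 of 21, with 0 lower in each. Taken over the cells of all libraries together, the 10 genes with the highest fold held the cardiac marker TNNT2 in both clusters. Those of cluster 7 also held OSR1, a marker of intermediate mesoderm that is also on the lateral plate list. Neither set held a fixed marker of limb and lateral plate mesenchyme. Both clusters are called by number, while the other classes keep the authors' names. Primitive mesoderm at HH10 had MSGN1 at 102 CPM, 7.81-fold above cluster 7 (5.71 to 10.9), and TBX6, WNT3A and FGF8, genes of presomitic mesoderm and the streak, were 11.1-fold, 5.93-fold and 4.37-fold higher there. At HH10, 678 genes were higher in cluster 1 and 117 in cluster 7, a split of 85.3%, and after median-of-ratios scaling 405 and 211, a split of 65.7%.

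**Figure D4:**
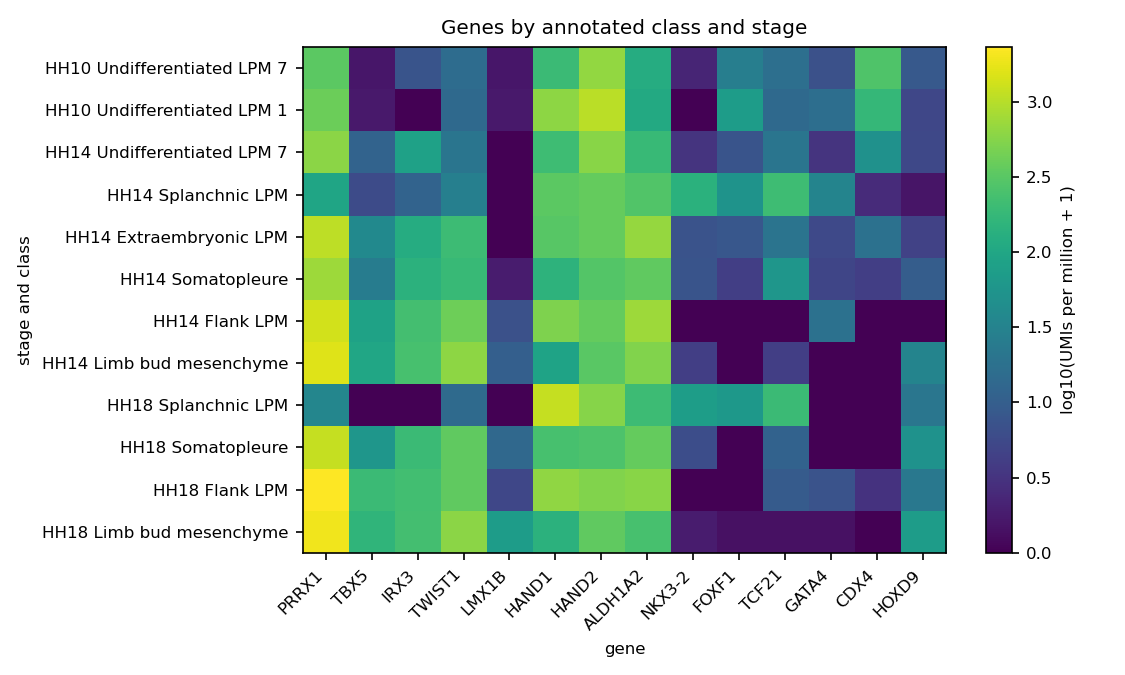
Levels of 14 genes (columns) in 12 combinations of stage and annotated class (lines of the grid), coloured by log10 of CPM plus 1. Among those shown, NKX3-2 is highest in splanchnic lateral plate at HH14 with 139 CPM and LMX1B in limb bud mesenchyme at HH18 with 71.4 CPM.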

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

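Of the tests in this part, the share of haemoglobin in the cells with the most at HH14 was set before its result was seen, and the others, including the limit of 5 HINTW UMIs, were chosen afterwards.

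Low count cells, a class the authors set apart, held PRRX1 at HH18. In 93 such cells PRRX1 was at 1306 CPM (1178 to 1444), against 51.6 CPM (23.6 to 97.9) in blood vessel cells of the library, while TBX5 was at 44.8 CPM (23.9 to 76.6) against 11.5 CPM (1.39 to 41.4), with overlapping intervals. No explanation was tested for these levels.

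HINTW, a W-linked gene of female birds, was at 1584, 3779 and 3664 CPM over all cells at HH10, HH14 and HH18. With cells thinned to 2800 UMIs, 38.2%, 67.0% and 78.0% had a HINTW UMI, and the smaller ratio of these shares to HH10 was 1.75. This is consistent with more female cells in the later pools. A higher level per female cell is argued against by cells with 5 or more HINTW UMIs, whose mean was at most 1.07 times that at HH10, while over all positive cells the ratios of 1.05 and 1.24 left it open. Whether sex mix affects the comparisons of stages was examined by selecting cells. With cells of 5 or more HINTW UMIs 195 values of named genes stayed and 64 moved, and with cells of 0 HINTW UMIs 173 stayed and 71 moved. None with a main fold of 2 or more changed direction. The selections kept 147, 301 and 196 cells, and 343, 179 and 69 cells, at HH10, HH14 and HH18. Values were judged against counting intervals of the whole population, and no other selection of the same size was run. The moves therefore cannot be assigned to sex mix or to fewer cells.

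Haemoglobin UMIs lay in 19.2%, 96.7% and 97.8% of lateral plate and limb mesenchyme cells at HH10, HH14 and HH18. At HH14 the 6 cells with the most held 49.0% of them and at HH18 the 4 cells with the most 19.4% (18.01 to 20.96), which neither shows nor excludes a few doublets with red blood cells. Of the 5311 haemoglobin UMIs at HH14, 1 extraembryonic lateral plate cell held 2130. Over all cells, gene proportions differed from red blood cells of the same library by up to 3.90 percentage points at HH14 and 5.001 at HH18, and the highest class was at 4.996 and 2.84 times the median class. At HH18 that class was somatopleure, 15.7 points from red blood cells with 3 of the 4 top cells, so free RNA and expression in 1 class cannot be told apart for the whole signal because the top cells weigh on both values. In the other 592 and 321 cells the proportions differed by up to 1.23 and 1.37 points, a closeness that free RNA of red blood cells would give. Splanchnic cells at HH18, with 143 haemoglobin UMIs, differed by 10.2 points. The highest class was 1.43 and 1.24 times the median class in these other cells. That ratio cannot decide on expression in 1 class, because the cells left out were chosen by their haemoglobin. They came from extraembryonic lateral plate and somatopleure at HH14 and mostly from somatopleure at HH18.

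CDX4 and EVX1 were higher in the HH10 library. Within classes present at both stages, the smallest fold was 1.62 (1.04 to 2.66), for CDX4 in undifferentiated cluster 1, and the others ran from 3.28 to 21.5, with blood vessel cells at 32 and 0 UMIs of CDX4. A different class mix therefore may account for part of the difference, and the test left its share open. A dissection reaching further posterior at HH10 would raise HOX genes of paralog group 9 there. Their median log2 fold of HH14 over HH10 was -0.45 over 4 genes, from -1.52 to -0.19, which leaves that explanation and a change with stage open.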

How the results depend on the processing

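The alternatives without somatopleure, with amnion, without splanchnic and extraembryonic classes, by HINTW UMIs, and of median-of-ratios scaling between classes were chosen after the data were seen. No paired analysis was possible because each stage has 1 library. Over the alternatives, 3174 values of named genes stayed within their counting interval, 583 moved beyond it and 9 changed direction. For list medians these numbers were 236, 58 and 6, and for summary values 122 stayed and 73 moved, where a count of genes stayed if it was within 1.5 times its main value. A change of direction was counted only for genes with a main fold of 2 or more. For lists it was counted only where the median lay in either tail of the random lists. Other changes of sign are among the values that stayed or moved. Of the named gene values that stayed, 308 came from the minimum of 10 UMIs, 237 from that of 100 UMIs and 308 from leaving out doublets. These settings could not move a gene's fold, so those values say nothing about stability. A minimum leaves the fold itself unchanged, and no mesenchyme cell was called a doublet.

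The counts of genes past the fold threshold depended on the minimum of UMIs, the fold and the cells used. For HH14 over HH10, HH18 over HH14 and HH18 over HH10 in turn, a minimum of 10 UMIs gave 757 higher and 437 lower, 626 and 515, and 1144 and 636. A minimum of 100 UMIs gave 156 and 101, 143 and 126, and 340 and 197. A fold of 4 gave 120 and 56, 71 and 89, and 200 and 171. Thinned cells gave 242 higher for HH14 over HH10, 194 higher and 162 lower for HH18 over HH14, and 375 higher for HH18 over HH10, and list members lower at HH18 than at HH14 numbered 18. With cells in S or G2/M phase left out by calls made here on thinned cells, which kept 16, 28 and 8 cells the counts were 80 and 47, 53 and 41, and 85 and 79. The authors' calls give 265, 293 and 130 cells in G1, an alternative that was not run.

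All annotated cells gave 712 genes higher at HH14 than at HH10. Without splanchnic and extraembryonic classes, 220 genes were higher at HH14 than at HH10 and 124 lower at HH18 than at HH14. Cells with 5 or more HINTW UMIs gave 152 genes lower at HH14 and 220 lower at HH18, each against HH10. The cause was not tested.

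Over all annotated cells, log2 folds turned to 0.0355 for MSX1 and 0.82 for CYP26B1 (HH14 over HH10), 0.46 for CLDN1 and 0.17 for CLDN3 (HH18 over HH14), and -0.13 for FGF10, 0.67 for ITGA6 and 0.88 for CYP26B1 (HH18 over HH10). With amnion added they turned to 0.20 for MSX1 (HH14 over HH10) and 0.19 for CYP26B1 (HH18 over HH10). These alternatives add cells of other classes.

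In thinned cells the list medians turned to -0.12 for lateral plate mesoderm and -0.0269 for Hedgehog genes (HH14 over HH10), to 0.13 for extracellular matrix and 0.0243 for haemoglobin genes (HH18 over HH14), and to -0.0244 for cartilage, tendon and connective tissue genes (HH18 over HH10). Fewer genes were measured in thinned cells, at 6793, 6321 and 6264 against 9166, 9064 and 8953 for the successive pairs. The thinned medians can therefore be over fewer members of a list. The mean over cells gave 0.11 for haemoglobin genes (HH18 over HH14). The cause of these changes was not tested.

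The share of lateral plate and limb mesenchyme was 6.03%, 30.1% and 58.5% at HH10, HH14 and HH18 with new clusters, which hold partly other cells at each stage, and 48.2% at HH18 in cells with at least 2583.1 UMIs. Between classes, median-of-ratios scaling gave 612 genes higher and 256 lower in limb bud mesenchyme than in somatopleure at HH18, and 405 higher and 211 lower in undifferentiated cluster 1 than in cluster 7 at HH10.

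Shares of cells with a UMI of FGF10, ALDH1A2, PRRX1 and TBX5 were higher at greater depth. Without thinning they were 8.51%, 10.7% and 28.0% for FGF10 at HH10, HH14 and HH18, 36.9%, 74.1% and 67.7% for ALDH1A2, 69.6% and 67.7% for PRRX1 at HH10 and HH14, and 14.2% and 52.3% for TBX5 at HH14 and HH18. At 4200 UMIs they were 5.27% and 7.37% for FGF10 at HH10 and HH14, 32.7%, 68.3% and 57.0% for ALDH1A2, 63.5% and 67.0% for PRRX1 at HH10 and HH14, and 8.26% and 36.9% for TBX5 at HH14 and HH18. Depth therefore limits what these shares show.

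Cell cycle genes kept their order of stages under each alternative run. As a mean over cells, S phase genes were at 4590, 5019 and 5461 CPM and G2/M genes at 7546, 8115 and 9046. With totals without haemoglobin, mitochondrial and ribosomal protein genes they were at 6702, 7431 and 7791, and at 11238, 11741 and 13013. Leaving out doublets removed 0 cells of lateral plate and limb mesenchyme and so says nothing about stability.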

Other observations

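The division of the intermediate mesoderm class was examined only after the data were seen, while folds between classes of a library were planned. The class that the authors call intermediate mesoderm held 88 cells. Its 10 genes with the highest fold included 4 markers of neural tube (OLIG2, PAX6, NKX6-1 and HES5) and 1 of intermediate mesoderm (LHX1). New clusters named by fixed markers placed 28 of the cells in intermediate mesoderm, 32 in neural tube and 18 in somite. In the 28 cells LHX1 was at 867 CPM, PAX2 at 334 CPM and OLIG2 at 0 UMIs, and in the 32 cells OLIG2 was at 433 CPM, HES5 at 569 CPM, NKX6-1 at 296 CPM and LHX1 at 0 UMIs. This class was therefore not compared between stages by name.

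In the HH18 library, the second ectoderm cluster had some genes of the apical ectodermal ridge, the signalling epithelium at the limb tip, above the first. Among its 10 genes with the highest fold, taken over the cells of all libraries together, WNT6 and WNT7A are surface ectoderm markers and SP8 a ridge marker. FGF8 had 1 UMI in the first cluster and stood at 88.0 CPM in the second (34.4-fold, 6.01 to 1375), SP8 had 3 and 79 UMIs, while BMP2, also on the ridge list, was 2.38-fold higher in the first. The first cluster had KRT17 29.8-fold higher. Its genes with the highest fold over all libraries included UPK1B and UPK3B, markers of mesothelium and coelomic epithelium, and GRHL3, a surface ectoderm marker. In the first cluster surface ectoderm markers summed to 8819 CPM and mesothelium markers, which share KRT18 and KRT19 with them, to 3619 CPM, so ectoderm is the authors' name for it.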
